A study of Mus musculus with 6 samples.

How the data were processed

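Whole lenses of adult mice were profiled by RNA sequencing, with 2 lenses per sample, 3 samples from animals with a germline deletion of Cd24a and 3 from wild-type animals. Per the labels' protocols, ribosomal RNA was depleted, stranded total RNA libraries were made for low input, and single-end reads were taken on 4 lanes per library. The submitters' processing notes name HISAT2, HTSeq, edgeR and the mouse build GRCm39, without versions, roles or settings. The strand setting of the counting is not given in the sources used here. The age is 8 weeks in the sample labels and 7 weeks in the series text. The strain label differs between the groups, C57BL/6 for the knockout and C57BL/har for the wild type, so strain and genotype cannot be separated in this design. The labels describe the samples of a group as biological replicates.

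The authors deposited raw read counts per gene, 1 column per library, on the features of Ensembl release 104, per the file headers and the description sheet. They also deposited a length in bp and a GC fraction for each feature. The authors' deposited comparison tables give a signed fold change (used here as a score that is never between -1 and 1), p-values from edgeR with Storey q-values, and the mean FPKM of each group. The authors' list of 2-fold changes used a fold over 2 and a q-value under 0.05, per the description sheet, and their shorter list added criteria on FPKM. The count table held 55416 genes and no row without a gene identifier. No column of per-sample values was left unmapped.

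Everything else was computed from the deposited counts. Totals ran from 5384542 to 7302951 counts per library, and CPM (counts scaled to a fixed library total) were scaled by TMM factors. Genes were filtered with filterByExpr on genotype, which left 11474 genes holding at least 99.6% of the counts of each library after rounding, and genotype was tested with the edgeR quasi-likelihood test (edgeR 4.0.16, limma 3.58.1, R 4.3.3), two-sided, with Benjamini-Hochberg adjustment. A gene was called at an adjusted p of at most 0.05. Errors of log2 fold changes were taken as the size of the fold change divided by the square root of its F statistic. SDs are over 3 libraries per group. The common biological coefficient of variation was 7.19%. Intervals and floors from counts cover counting error only, since the libraries carry no molecular identifiers. A gene with no count in a whole group was given a lower bound of its fold against a floor of 3 counts over that group.

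The 20 gene lists and 10 lists of markers of other tissues or of sex and strain were fixed before the data were examined. So were the rule for named genes and the tests, except those given as added or chosen later. The tests of each chromosome and of windows of 10 Mb along the genome were not fixed beforehand. Lists with at least 3 tested members (27 of 30) were compared with all other genes by camera on log2 CPM (prior count 2, preset correlation 0.01), adjusted over lists. Shares of counts were compared by exact permutation tests, two-sided, over 20 arrangements, which cannot give a p below 0.10. Calls within 10 Mb of Cd24a were compared with the rest of the genome by Fisher's exact test, with gene order and biotypes from GENCODE M21 on GRCm38, matched by Ensembl identifier. That annotation is on another build than the counts and gave a biotype for 11443 of the tested genes. The named genes were Cd24a, the 10 protein-coding genes with the largest increase and the 10 with the largest decrease among calls with a mean of at least 1 CPM and no overlap between the groups, up to 4 called members of each list, 12 fixed lens genes, and up to 2 abundant members of each marker list. Some named genes are not reported here. Other genes are named as chosen after their values were seen.

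The fit was tested on simulated counts with 200 of 11223 tested genes changed in the knockout group. Of 50 genes changed by each size, it recovered 6 at 1.25-fold, 28 at 1.5-fold, 37 at 2-fold and 49 at 4-fold, with 7 calls among unchanged genes. With no gene changed it called 3 genes of 11250 and 0 lists. The simulated genes were drawn independently of each other, so this cannot tell how often lists of genes that vary together are called falsely. Alternatives were other scalings, other filters, DESeq2 1.42.0, limma-voom, the edgeR exact test, a replicate block, leaving out each library, camera with an estimated correlation, fry, and other windows around Cd24a. A term for Xist reads, a photoreceptor marker score as covariate, and a correction for GC content and length were added after the data were seen. Coordinates are not printed, since no annotation of GRCm39 was used here.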

Results

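The transcriptome of the whole mouse lens was compared between animals lacking Cd24a, which encodes a small glycosylphosphatidylinositol-anchored surface glycoprotein, and wild-type animals. Each group held 3 samples of 2 lenses. The libraries held 5384542, 5966090 and 5430686 gene counts in the knockout group and 7302951, 6818687 and 6262742 in the wild-type group. The first principal component of log2 CPM took 43.7% of the variance and separated the genotypes. No pair of libraries agreed within sampling noise, with a chi-square per degree of freedom of 2.80 or more. Xist, the noncoding RNA of the inactive X chromosome, was abundant in replicate 3 of each group (2466 and 2191 counts) and had at most 4 counts in the other libraries. The Y-linked genes Ddx3y and Uty had 0 counts in replicate 3 of each group and 87 to 311 in the other libraries. Each group thus held 1 library with a female pattern, and the others had a male pattern.

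Cd24a (ENSMUSG00000047139, chromosome 10) was abundant in wild-type lenses and nearly absent in every knockout library. Its level was 2910 ± 67.9 CPM in wild type and 10.04 ± 2.40 CPM in the knockout (SD, n = 3 each). The counts were 20656, 18730 and 17514 in wild type against 71, 58 and 45 in the knockout. The log2 fold change was -8.18 (SE 0.10, edgeR quasi-likelihood adjusted p = 1.63e-22), and every library followed its genotype label.

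The deletion was accompanied by many small differences. Of 11474 genes tested, 861 passed the threshold, 347 higher and 514 lower in the knockout. Of these calls, 499 (58.0%) were under 1.5-fold, and 179 reached 2-fold, 49 higher and 130 lower. At an unadjusted p of at most 0.05 there were 2320 genes. The groups did not overlap for 2803 tested genes (24.4%, where chance gives 10%). Scaled by library size alone, which moved the median log2 fold change of all genes from 0.004 to 0.114, the fit called 1344 genes, 1008 higher and 336 lower. RLE, upper-quartile scaling and TMM without crystallins and mitochondrial genes called 340, 361 and 341 higher and 509, 501 and 517 lower. Among the scalings tried, library size alone thus reversed the split by direction. Leaving out knockout replicate 1 left 562 calls, and the higher calls numbered 194 without knockout replicate 1 and 196 without wild-type replicate 1.

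**Figure D1:**
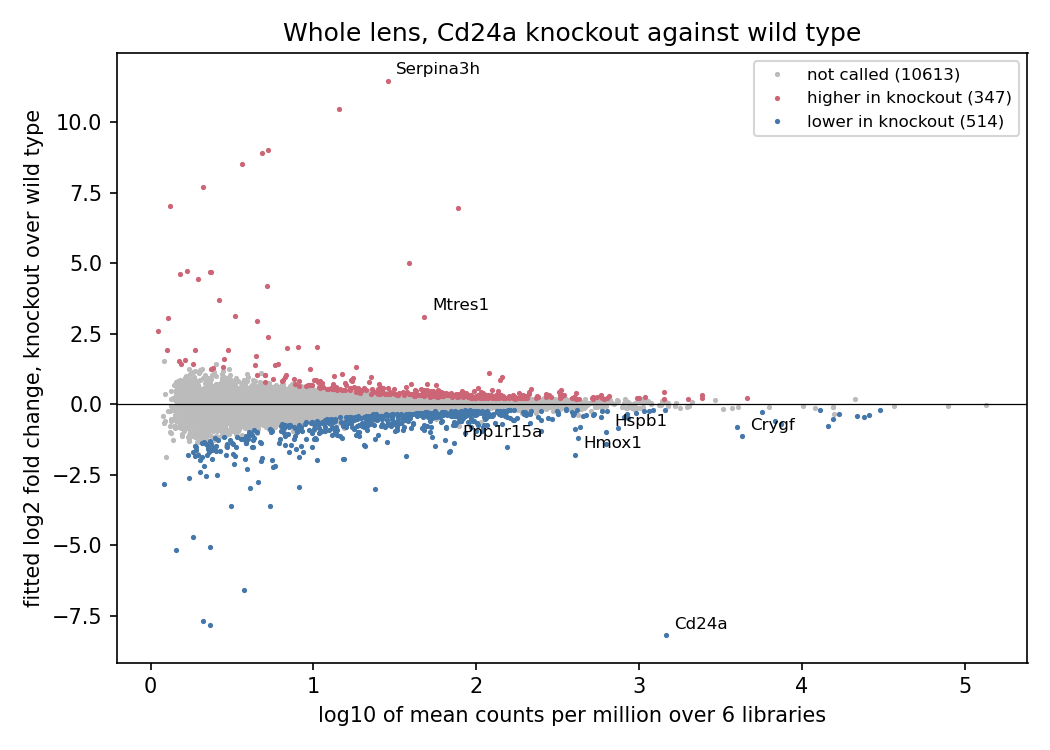
Fitted log2 fold change of each of the 11474 tested genes, knockout over wild type, against the log10 of its mean CPM over the 6 libraries, with genes called higher (347), lower (514) or not called (10613) in colour. Cd24a lies apart at -8.18, and most calls lie close to 0.

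Among protein-coding genes, the largest increases included members of the Serpina3 cluster of serine protease inhibitors on chromosome 12. Serpina3i had 0 counts in wild type and 28.9 ± 2.36 CPM in the knockout (SD, n = 3), at least 189-fold higher, and Serpina3f had 0 counts and 10.5 ± 0.55 CPM, at least 68.6-fold higher. Mtres1, a mitochondrial transcription rescue factor and the nearest tested neighbour of Cd24a on the lower-coordinate side, rose from 9.93 ± 2.26 to 85.0 ± 1.51 CPM (log2 3.10, SE 0.11). Rps18-ps6, a ribosomal protein pseudogene annotated as coding in M21, rose from 2.31 ± 0.20 to 74.5 ± 10.7 CPM. Tpm3-rs7, Rgs5, a regulator of G protein signalling, Dnah8, an axonemal dynein chain, and Gm14326, Gm14295 and Gm14325, a group of genes on chromosome 2, rose by 1.93 to 3.71 on the log2 scale. Reads of Rps18-ps6, Tpm3-rs7, the Serpina3 genes and the chromosome 2 group may be shared with near-identical copies, so these values are uncertain. Whether the value of Mtres1 depends on the strand setting of the counting was not tested. The 3 chromosome 2 genes lost their calls in DESeq2, at adjusted p = 0.29 to 0.45.

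The largest decreases after Cd24a were in genes of low abundance. Bdkrb2, the bradykinin B2 receptor, was at 2.81 ± 0.25 CPM in wild type and had 1 count in total in the knockout. Emilin2, an extracellular matrix glycoprotein, fell from 5.81 ± 0.69 to 0.44 ± 0.47 CPM. Alox15, a lipoxygenase, Sall3, a zinc-finger transcription factor, Rpe65, the retinoid isomerase of the retinal pigment epithelium, H2-K1, a classical MHC class I gene, and Myo7b, an unconventional myosin, fell by 2.23 to 2.63 on the log2 scale. Gm15446 and Lrrn1, a leucine-rich repeat membrane protein, had log2 fold changes of -4.71 and -2.99, and Lrrn1 was at -6.05 without knockout replicate 2 and lost its call in DESeq2 (adjusted p = 0.23).

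Crystallins, the structural proteins of the lens, differed by family. All 8 γ-crystallin genes fell, led by Cryga (914 ± 223 to 340 ± 82.5 CPM, log2 -1.43, SE 0.14), Crygf (5850 ± 443 to 2657 ± 211 CPM, log2 -1.14, SE 0.07), Crygd (log2 -0.78) and Cryge (log2 -0.70), and Crygs fell by 0.37. Of 6 β-crystallins 4 fell (3 with RLE, upper-quartile scaling or library size alone) and of 2 α-crystallins neither passed. Cryaa was at 81202 ± 3930 CPM in wild type and 76959 ± 4498 CPM in the knockout, Cryab had a log2 fold change of -0.08 and Crybb2, the most abundant, -0.03. The median α-crystallin change went from -0.08 to 0.03 when library size alone was used, while the γ-crystallin median stayed negative under every scaling (-0.58 to -0.47). γ-crystallins took 11.2% ± 0.40 of wild-type counts and 8.36% ± 0.34 of knockout counts (SD, n = 3, exact permutation p = 0.10, the smallest possible), whereas α-crystallins took 11.4% ± 0.23 and 11.6% ± 0.32. All crystallins together took 44.2% ± 0.64 and 41.3% ± 1.32 (exact permutation p = 0.10). Of 16 crystallins 12 were called lower and 0 higher, also 12 adjusted over the list alone (camera adjusted p = 8.34e-09, but adjusted p = 0.34 with an estimated correlation). Crygd, Cryge, Crygf and their close relatives share long stretches of sequence, so the split of reads between them is uncertain.

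**Figure D2:**
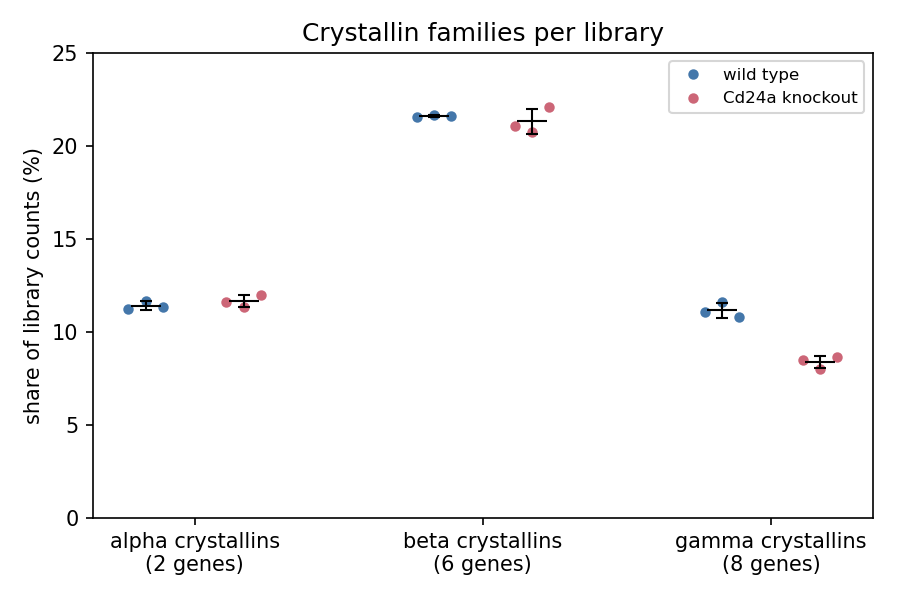
Share of each library's gene counts, in percent, taken by the α, β and γ crystallins, with each library as a point and the mean ± SD of 3 libraries in black. The γ share is 11.2% in wild type and 8.36% in the knockout with no overlap, whereas the α and β shares overlap.

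Other genes of lens fibre cells fell more often than they rose. Birc7, an inhibitor of apoptosis protein, went from 331 ± 25.8 to 169 ± 11.9 CPM (log2 -0.97, SE 0.07, edgeR adjusted p = 4.66e-09). Grifin, a lens galectin-related protein, Fabp5, a fatty acid binding protein, and Lctl, a klotho family member, fell by 0.50, 0.35 and 0.33 on the log2 scale. Bfsp2, the beaded filament protein phakinin, fell by 0.27, from 6244 ± 115 to 5173 ± 251 CPM. With library size alone Lctl and Bfsp2 had log2 fold changes of -0.22 and -0.16 and stayed called. Bfsp1, Mip (the fibre cell aquaporin), Gja3 and Prox1 had log2 fold changes between -0.15 and 0.02 (-0.04 to 0.13 with library size alone) and did not pass. Of 20 fibre genes tested 8 were called lower and 1 higher (10 and 1 adjusted over the list alone), with camera adjusted p = 9.76e-04 and adjusted p = 0.45 with an estimated correlation. The higher gene was Nrcam, a neuronal cell adhesion molecule, at log2 0.23, whose call was lost with a photoreceptor marker score in the model (adjusted p = 0.064).

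Genes of the lens epithelium were called lower in 6 of 18 cases and higher in none, and 10 were lower adjusted over the list alone. Aqp1, a water channel, fell from 30.2 ± 4.92 to 10.96 ± 2.17 CPM (log2 -1.45, SE 0.15). Npnt, the matrix protein nephronectin, Gja1, connexin 43, and Igfbp7, an insulin-like growth factor binding protein, fell by 0.48, 0.41 and 0.34. Pax6 and Foxe3, transcription factors of lens identity, had log2 fold changes of 0.02 and 0.05 (0.13 and 0.15 with library size alone) and did not pass. The list had camera adjusted p = 9.76e-04, and adjusted p = 0.34 with an estimated correlation. Ion and water transport genes included 5 lower and 1 higher of 22 (6 and 1 adjusted over the list alone), with Slc12a2, a sodium-potassium-chloride cotransporter, at log2 -0.41, Atp1b1, a sodium pump subunit, at -0.45 and Atp1b3 at -0.30, whose call was lost without knockout replicate 1 (adjusted p = 0.051) or with library size alone (log2 -0.18, adjusted p = 0.070). That list had camera adjusted p = 0.032 and adjusted p = 0.28 with an estimated correlation, and lost its call without knockout replicate 3 (adjusted p = 0.075) or wild-type replicate 3 (0.10) or with the photoreceptor score (0.15).

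Lists on adhesion, matrix and CD24 signalling gave few calls. Of 7 CD24 binding partners tested none was called by edgeR, DESeq2 or limma-voom, with 1 at an unadjusted p of at most 0.05, and the list had camera adjusted p = 0.57. Of 19 adhesion and Eph-ephrin genes Nrcam alone was called (camera adjusted p = 0.24). Of 17 capsule and basement membrane genes none was called by edgeR (5 at an unadjusted p of at most 0.05), DESeq2 called 2 and limma-voom 3, and the list did not pass (camera adjusted p = 0.34). Of 14 epithelial-mesenchymal transition and fibrosis genes S100a4, a calcium-binding protein, fell by 1.13 and Acta2, smooth muscle actin, fell by 0.53, from 347 ± 13.9 to 240 ± 8.69 CPM, whereas Ltbp1, a latent transforming growth factor binding protein, was called higher at log2 0.48. The call of Ltbp1 was lost without knockout replicate 1 or 2 or wild-type replicate 2 (adjusted p = 0.11). Adjusted over the list alone, 3 of these genes were higher and 2 lower. Their median was 0.09, while the mean and the test pointed down (camera adjusted p = 0.82).

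Genes of the unfolded protein and integrated stress response were lower in the knockout in 8 of 19 cases and higher in none (12 and none adjusted over the list alone). Ppp1r15a, a phosphatase subunit that reverses eIF2α phosphorylation, fell from 105 ± 5.06 to 41.0 ± 6.74 CPM (log2 -1.37, SE 0.09). Hspa5, the endoplasmic reticulum chaperone BiP, fell by 0.50, Atf4, a stress-responsive transcription factor, by 0.46 and Pdia6, a disulfide isomerase, by 0.44. Camera gave the list adjusted p = 1.02e-06, and adjusted p = 0.12 with an estimated correlation. Oxidative stress genes were lower in 6 of 22 cases and higher in none, also 6 and none adjusted over the list alone. Hmox1, heme oxygenase 1, fell from 622 ± 44.7 to 181 ± 17.5 CPM (log2 -1.79, SE 0.07, edgeR adjusted p = 2.94e-13), and Slc7a11, a cystine transporter, from 82.3 ± 5.97 to 29.2 ± 3.60 CPM (log2 -1.50, SE 0.09). Prdx6, a peroxiredoxin, fell by 0.43, and Cat, catalase, had log2 -0.24 and lost its call without each of 4 libraries (knockout replicates 1 and 2, wild-type replicates 1 and 2; adjusted p = 0.088 to 0.18) or with library size alone. The oxidative list had camera adjusted p = 0.044, and adjusted p = 0.42 with an estimated correlation. Its call was lost without knockout replicate 2 (adjusted p = 0.34), wild-type replicate 2 (0.13) or wild-type replicate 3 (0.085), with no low-count filter (0.13), with a term for Xist reads (0.059) or the photoreceptor score (0.0503), and with library size alone (0.069), where its median moved from -0.09 to 0.02.

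**Figure D3:**
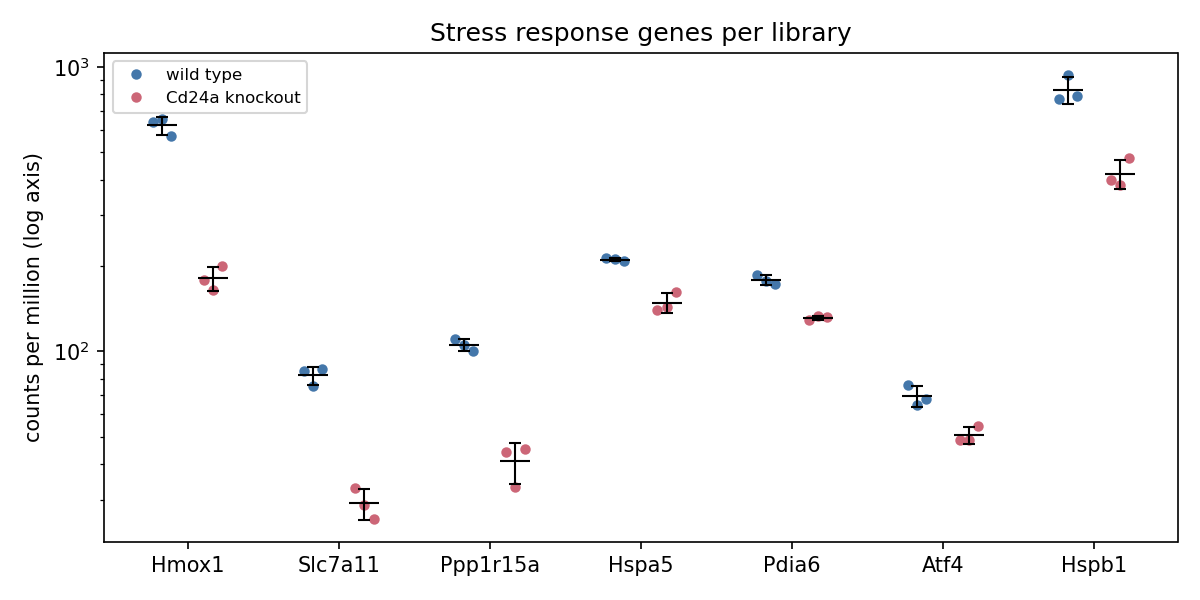
CPM on a log axis of 7 stress response genes in each library, wild type and knockout, with the mean ± SD of 3 libraries in black. The groups do not overlap for any of the 7, and Hmox1 lies at 622 in wild type and 181 in the knockout.

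Heat shock genes went both ways. Hspb1, a small heat shock protein, fell from 831 ± 89.2 to 421 ± 50.5 CPM (log2 -0.98, SE 0.08), while Hsp90ab1 and Hspa8, cytosolic chaperones, were called higher at log2 0.22 and 0.20. The call of Hsp90ab1 was lost without wild-type replicate 3 (adjusted p = 0.051) or with the photoreceptor score (0.057), and that of Hspa8 without knockout replicate 1 or 3 or wild-type replicate 1 or 2 (adjusted p = 0.073 to 0.17), in the edgeR exact test (0.067) or with the photoreceptor score (0.13). The list of 14 did not pass (camera adjusted p = 0.17; 2 higher and 2 lower adjusted over the list alone). Among 13 immediate early genes Klf6, a transcription factor, rose by 0.53 and Ccn2, a matricellular growth factor, fell by 0.81 (camera adjusted p = 0.82, median 0.004 with the mean below 0). Ccnd1, cyclin D1, and Cdkn1c, a cyclin-dependent kinase inhibitor, rose by 0.38 and 0.35 among 20 cell cycle genes (camera adjusted p = 0.14, and 0.039 with no low-count filter). These 2 lists gave the same counts adjusted over the list alone.

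Of 21 cholesterol synthesis genes Insig1, a regulator of sterol sensing, fell by 0.30, and Hmgcs1, an early enzyme of the pathway, was called higher at log2 0.29 (camera adjusted p = 0.054). The list passed with no low-count filter (adjusted p = 0.022), with at least 1 CPM in 3 libraries (0.044), without knockout replicate 2 (0.039) or wild-type replicate 1 (0.041) and with the photoreceptor score (0.043). The call of Hmgcs1 was lost without knockout replicate 1 or 2 or wild-type replicate 2 or 3 (adjusted p = 0.082 to 0.17) and in DESeq2 (0.057), and that of Insig1 with library size alone (adjusted p = 0.12). Of 21 glycolysis and hypoxia genes Aldoc, an aldolase, and Ldha, a lactate dehydrogenase, were called lower at log2 -0.28 and -0.29, with 3 lower adjusted over the list alone. That list had camera adjusted p = 0.0080, and adjusted p = 0.26 with an estimated correlation. With library size alone both calls were lost (adjusted p = 0.077 and 0.13), and that of Ldha also without knockout replicate 1 or 2 or wild-type replicate 1 or 2 (adjusted p = 0.082 to 0.15), in DESeq2 (0.070) or with the photoreceptor score (0.055). Of 9 mitochondrially encoded genes none was called by edgeR, DESeq2 or limma-voom, with 3 at an unadjusted p of at most 0.05 (camera adjusted p = 0.28, and 0.015 with the photoreceptor score). Fyco1, an autophagy adaptor, was the 1 gene called among 28 inherited cataract genes (log2 0.25, camera adjusted p = 0.81), and its call was lost without knockout replicate 1 or any wild-type library (adjusted p = 0.054 to 0.098). The median of the cataract genes lay below 0 and the test pointed up.

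Immune genes were scarce. Of 26 inflammatory mediators 2 had enough counts to be tested and neither was called by edgeR, DESeq2 or limma-voom (1 at an unadjusted p of at most 0.05). H2-K1 fell from 6.57 ± 1.83 to 1.302 ± 0.37 CPM and Tap2, a peptide transporter of antigen presentation, by 1.42 on the log2 scale, which were the 2 calls among 8 MHC class I and antigen presentation genes. That list had camera adjusted p = 0.036 and adjusted p = 0.34 with an estimated correlation, and lost its call without knockout replicate 3 or wild-type replicate 1 or 3 (adjusted p = 0.056 to 0.076). Mx2, of the family of interferon-induced dynamin-like GTPases, is annotated as a polymorphic pseudogene in M21. It rose from 0.26 ± 0.24 to 2.30 ± 0.08 CPM (5 counts in total in wild type and 40 in the knockout) and was the 1 call among 8 interferon response genes. The interferon list had camera adjusted p = 0.054 and passed without wild-type replicate 1 (adjusted p = 0.041) or 2 (0.028), with no low-count filter (0.039), with fry (0.0089) and with the Xist term (0.041) or the photoreceptor score (0.047).

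**Figure D4:**
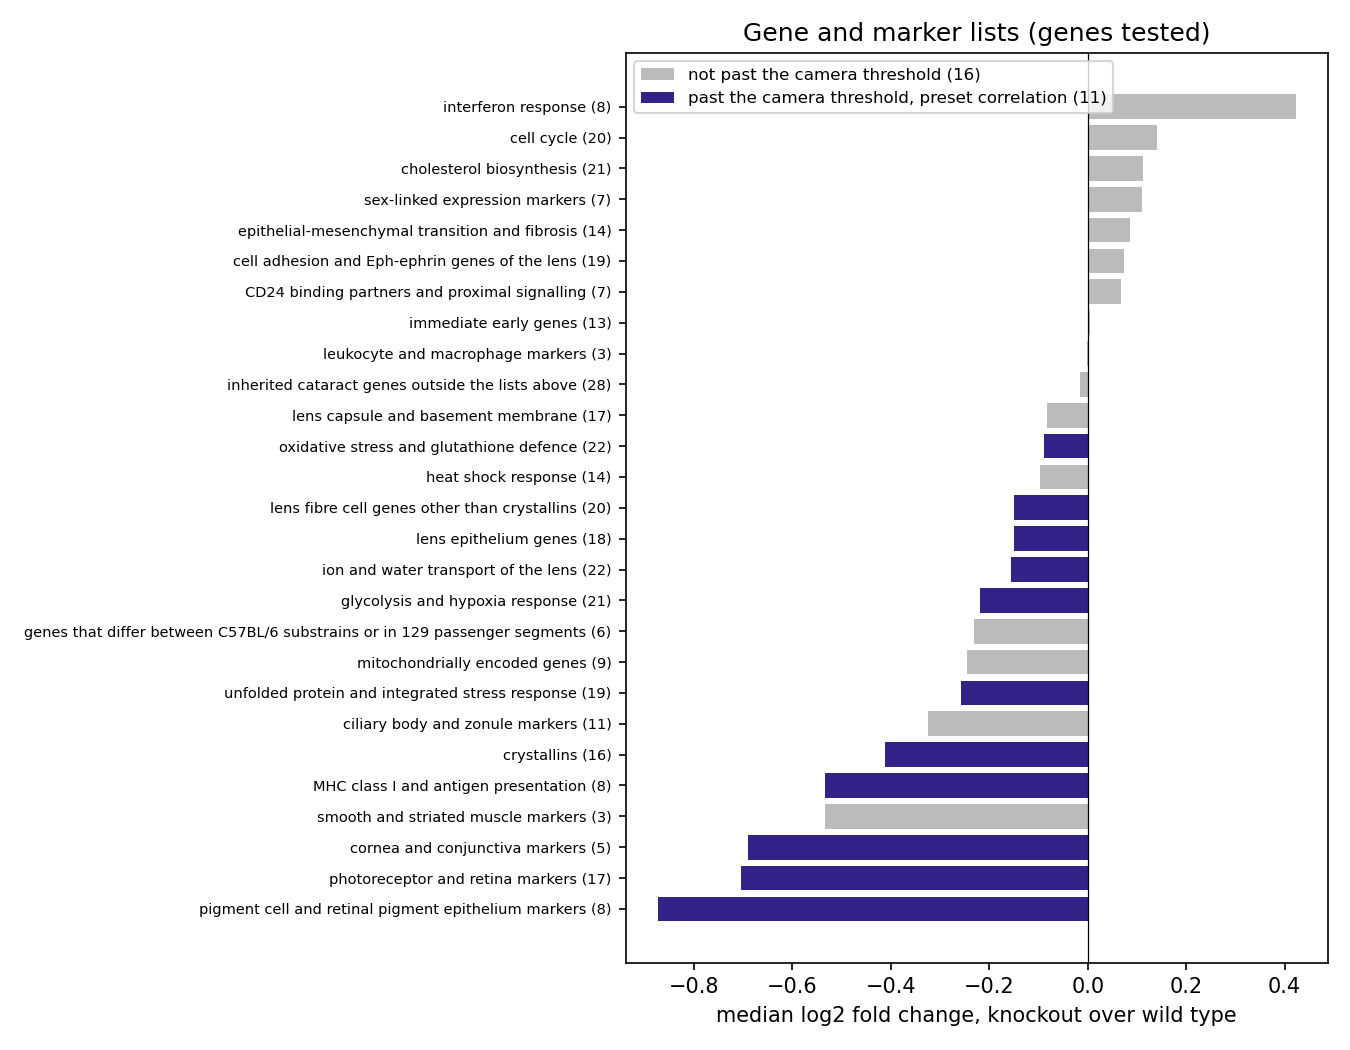
Median fitted log2 fold change, knockout over wild type, of each of the 27 lists with at least 3 tested genes, with the number tested in parentheses. The 11 lists past the camera threshold with the preset correlation are dark and all lie below 0, and none of them passed with an estimated correlation.

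Several markers of the pigment epithelium and some genes of the cornea list were lower in the knockout. Retinal pigment epithelium and pigment cell markers were lower in 4 of 8 cases (5 adjusted over the list alone), with Rgr, a retinal opsin, falling by 1.46, Ttr, a thyroxine and retinol carrier, by 1.12 and Oca2, a melanosomal protein, by 0.62. The call of Ttr was lost in DESeq2 (adjusted p = 0.13), and that of Oca2 in DESeq2 (adjusted p = 0.076) and without knockout replicate 1 or 3 or wild-type replicate 2 (adjusted p = 0.056 to 0.095). Mitf was at log2 -0.21 and not called. The list had camera adjusted p = 9.76e-04, and adjusted p = 0.26 with an estimated correlation. Of 14 cornea and conjunctiva markers 5 could be tested and 4 of these were called lower, also 4 adjusted over the list alone, with Ptgds, prostaglandin D2 synthase, at log2 -0.74, Aldh1a1 at -0.38, Krt19, a keratin, at -0.76 and Aldh3a1 at -0.46 (camera adjusted p = 5.46e-04, adjusted p = 0.20 with an estimated correlation). Aldh1a1 was at 441 and Ptgds at 128 CPM in wild type, whereas Krt12 and Kera, markers of corneal epithelium and stroma, had 0 counts in every library and Krt5, Krt14 and Lum at most 2 in any library. Photoreceptor markers had a median of -0.70 over 17 genes with 2 calls, Gnat1 and Pdc, and 9 adjusted over the list alone, but varied within the groups. Gnat1, a transducin subunit, was at 98.6, 41.8 and 109 CPM in wild type and 67.1, 36.7 and 38.1 CPM in the knockout. The photoreceptor list had camera adjusted p = 0.0070 and adjusted p = 0.65 with an estimated correlation, and lost its call without knockout replicate 3 or wild-type replicate 1 or 3 (adjusted p = 0.058 to 0.15) and with fry (0.45). Gnat1 and Pdc were not called in DESeq2 (adjusted p = 0.54 and 0.45), limma-voom (0.097 and 0.16) or with library size alone (0.082 and 0.083). Gnat1 also lost its call without knockout replicate 2 or 3 or wild-type replicate 1 or 3 and Pdc without each library but wild-type replicate 2 (adjusted p = 0.070 to 0.29). Gnb1, also expressed outside the retina, was at log2 -0.03.

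Other marker lists did not pass. Among 11 ciliary body and zonule markers none was called by edgeR, DESeq2 or limma-voom (1 at an unadjusted p of at most 0.05; camera adjusted p = 0.43). Fbn1, a fibrillin, was at 85.2 CPM in knockout replicate 2 and at 32.0 and 20.8 CPM in the other knockout libraries, and without that library the list passed (median -1.43, adjusted p = 0.0020). Fbn1 was called without that library (log2 -1.36, adjusted p = 4.55e-05) and with no low-count filter (adjusted p = 1.48e-07). Of 3 leukocyte markers none was called by edgeR, DESeq2 or limma-voom (1 at an unadjusted p of at most 0.05; camera adjusted p = 0.59), with Csf1r at log2 0.00 and Lyz2 at -1.17. Of 3 muscle markers Acta2 was called, with a median of -0.53 and a mean above 0 (camera adjusted p = 0.54). Bpgm, the 1 erythroid marker tested, was at log2 -0.13, and Flt1, the 1 endothelial marker tested, at -0.83, and neither was called, although Flt1 passed without knockout replicate 2 (log2 -1.78, adjusted p = 0.0024) and with no low-count filter (adjusted p = 0.021). Among markers too scarce to be tested, chosen after their values were seen, the β-globin genes Hbb-bs and Hbb-bt had 23, 4 and 5 counts and 5, 1 and 3 counts in the knockout libraries and Cdh5, an endothelial cadherin, 3, 4 and 2, all with 0 in each wild-type library, whereas Cd14, a monocyte marker, had 0 in each knockout library and 2, 3 and 1 in wild type. Of 7 sex-linked markers none was called, with 0 at an unadjusted p of at most 0.05 and 0 in DESeq2 and limma-voom (camera adjusted p = 0.78). The balance of the groups, with 1 library of female pattern in each, left this list little room to differ. Among 6 genes known to differ between C57BL/6 substrains or in passenger segments, Bfsp2 alone was called (camera adjusted p = 0.088, and 0.034 without knockout replicate 1). Adjusted over the list alone, lists given without such a count had the same numbers of calls, except for 1 gene lower in each of the inflammatory, leukocyte and endothelial lists and 1 higher and 1 lower in the muscle list.

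Genes near Cd24a were not detectably called more often than others. A germline deletion can travel with flanking chromosome from another strain, and the groups carry different strain labels. Within 10 Mb of Cd24a by GENCODE M21 on GRCm38, 2 of 58 tested genes were called, against 844 of 11384 elsewhere (3.45% against 7.41%, odds ratio 0.45, 95% interval 0.053 to 1.69, Fisher's exact p = 0.44). The 2 genes were Mtres1 and Marcks, a protein kinase C substrate, at log2 0.31. The interval does not exclude a modest excess. Calls were more frequent on chromosome 17, with 62 of 562 tested genes (odds ratio 1.57, Fisher's exact adjusted p = 0.045 over chromosomes). Its 18 calls at 2-fold were not a detectable excess (Fisher's exact adjusted p = 0.083). No other chromosome held a detectable excess. H2-K1, Tap2, Dnah8 and Emilin2 lie on chromosome 17. Windows of 10 Mb were tested one-sided for all calls and for 2-fold calls, each adjusted apart, a scan not fixed beforehand. A window on chromosome 2 passed for 2-fold calls (8 of 42 tested genes, Fisher's exact adjusted p = 3.29e-05) but not for all calls (0.17). A window on chromosome 18 passed for all calls (10 of 35, Fisher's exact adjusted p = 0.033) and held 0 at 2-fold. No other window passed by either criterion. Whether strain or genotype is the source cannot be told in this design.

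The authors' deposited table listed the same 11474 genes as present. In it, 805 genes had a q-value under 0.05, 305 higher and 500 lower, of which 764 were called here. Of the 187 genes in the authors' deposited table of 2-fold changes, 171 were called here, all in the same direction. Of the 82 genes in the authors' deposited table with added FPKM criteria, 26 higher and 56 lower, 80 were called here. The median absolute difference between the log2 fold changes of the authors' deposited table and those fitted here was 0.0001. The counts are the same, so the overlap is no independent evidence.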

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

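The term for Xist reads, the photoreceptor score and the GC and length correction were chosen after seeing the data. No named gene reversed a call in the alternatives that refitted genes, nor any list in those that tested lists (not DESeq2, limma-voom, the exact test or the GC and length correction), although the median of the oxidative stress list changed sign with library size alone (0.02). Of the 96 named genes, RLE, upper-quartile scaling and TMM without crystallins and mitochondrial genes left all 96 on the same side of the threshold, as did a filter of at least 1 CPM in 3 libraries, which kept 12602 genes against 11474, and the GC and length correction. Library size alone called 1344 genes, 1008 higher and 336 lower, sharing 683 with the 861, with a median shift of 0.114 that comes from the scaling itself. DESeq2 called 574 genes, 219 of them higher, shared 565 and lost 11 named calls; the cause was not tested. The photoreceptor score left 211 higher calls of 615 and ended the calls of the ion transport (adjusted p = 0.15), oxidative stress (0.0503) and photoreceptor lists (0.998, the list it is made of), while the interferon (0.047), cholesterol (0.043) and mitochondrially encoded lists (0.015) passed; the cause was not tested. GlmTreat against 1.2-fold called 287 genes where the 2-fold criterion gave 179, by its construction. Leaving out 1 library gave 562 to 782 calls, 194 to 297 of them higher and 368 to 485 lower, 149 to 212 at 2-fold, 7 to 12 lists, 124 to 148 of the authors' 2-fold genes, odds ratios near Cd24a of 0.55 to 0.85, and crystallin share differences of -3.54 to -2.22 points; fewer samples were tested. Camera with an estimated correlation passed 0 lists, with 4 at an unadjusted p of at most 0.05, against 11 with the preset correlation and 14 with fry, which added the fibrosis, interferon, heat shock and cell cycle lists (adjusted p = 0.0089 to 0.025) and dropped the photoreceptor list (0.45). Libraries with the same number had deviation correlations of 0.05, -0.03 and 0.03, and not every library correlated best with its own number, so the numbers were not read as pairing. A link by number is not excluded. The mitochondrial share was 1.84%, 2.22% and 1.47% in knockout replicates 1 to 3 and 1.81%, 2.15% and 1.54% in wild type, and Xist was abundant in replicate 3 of each group. The crystallin share was lowest in knockout replicate 2 but highest in wild-type replicate 2. With a replicate block 781 genes were called, 293 higher and 488 lower, of which 751 were shared, and the oxidative stress list had adjusted p = 0.072, Hspa8 0.064 and the interferon list 0.021. The windows of 5 and 20 Mb gave odds ratios of 0.33 and 0.66. With 5384542 to 7302951 counts per library, of which crystallins took over 40% in each, a gene of a few CPM rests on few counts, and in simulated data 6 of 50 changes of the smallest size were recovered.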

Other observations

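Small noncoding RNAs were called lower in the knockout more often than higher. Of 70 tested features under 300 bp 20 were called lower and 4 higher, with a median log2 fold change of -0.57, and of 34 small structured RNAs 12 were called lower and 2 higher. Rny1 and Rny3, the Y RNAs that bind the Ro60 protein, fell from 57.5 ± 16.4 to 16.2 ± 3.27 CPM and from 590 ± 98.7 to 256 ± 49.1 CPM (SD, n = 3). Snord15a and Snord17, guides of ribosomal RNA modification, fell by 1.95 and 1.97 on the log2 scale. Rprl3, annotated as an RNase P RNA-like gene, went the other way, from 1.23 ± 0.79 to 154 ± 23.6 CPM. These genes were chosen after their values were seen, and no test of the class was made. The short features called lower include several entries named 5S_rRNA. Reads of such repeated features and of Rprl3 may be shared with near-identical copies, so these values are uncertain.

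Several other lens transcripts stood apart, also chosen after their values were seen. Crybg3, a βγ-crystallin domain protein, fell from 105 ± 5.03 to 33.3 ± 3.72 CPM, Pacsin3, an endocytic adaptor, from 519.5 ± 16.5 to 282 ± 7.30 CPM, and Ccdc180 from 103.7 ± 7.04 to 32.6 ± 7.32 CPM. Glo1, glyoxalase 1, rose from 98.8 ± 8.35 to 181 ± 7.46 CPM, and Nhsl1 from 76.0 ± 8.67 to 164 ± 12 CPM. Col6a1 and Col6a2, neighbouring collagen VI genes on chromosome 10, fell by 1.54 and 1.70.

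In the 3 patterns that follow, the tests on neighbouring calls, on the γ to α ratio, on strain labels and on the scaling of stress genes were chosen only after the result was seen, and the GC and length correction and the photoreceptor score after the data were seen. Neighbouring genes changed together. On chromosome 12 Serpina3e-ps, Serpina3f, Serpina3h and Serpina3i had 0 counts in wild type and 50 to 371 counts in each knockout library, and on chromosome 17 H2-K2, Gm4152, AA388235 and H2-K1 were all lower. Of 17 neighbouring pairs of tested genes with 2-fold calls in 1 direction 7 lay outside chromosomes 2, 12 and 17, whose runs prompted the test, where 10000 shuffles gave a median of 1 and at most 7 (permutation p = 0.0003, which takes calls of neighbours as independent). These 7 were all lower: Col6a2 and Col6a1, Rny3 and Rny1, Slc7a11 and Gm6209, Ppp1r15a and Plekha4, Gm12408 and Ccdc180, 5830417I10Rik and 1500004A13Rik, and Tceal6 and Nxf7. The test does not tell why such neighbours were called together. Reads moving among the 14 Serpina3 genes counted are argued against by their sum, which was 5.38 higher in the knockout in log2 of CPM + 1. Outside the run only Serpina3n had counts, 7 to 17 per library, so the sum rests mostly on the run itself. It cannot speak to reads that the counting left out, whose settings are not given. Inherited differences between the strains away from Cd24a may account for the runs, but strain and genotype cannot be told apart because no strain label occurs in both groups, and Gm14326 at 0.43, 6.47 and 5.82 CPM also varied within wild type.

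γ-crystallins were lower while α-crystallins were not. Library scaling is argued against, since the log2 ratio of γ to α reads within libraries differed by -0.44, knockout minus wild type (-0.48 ± 0.03 against -0.03 ± 0.03, SD, n = 3). A GC or length trend shared by all genes is argued against, since after correction the median γ-crystallin log2 fold change was -0.60, from -0.58 before. That trend was fitted over all genes, so it cannot exclude a loss particular to short transcripts. Median lengths were 758 bp for γ, 1393.5 bp for β and 1777.5 bp for α crystallins, with medians of -0.58, -0.21 and -0.08. Tested features under 300 bp had a median of -0.57. Whether short transcripts as such were lost was not tested. A strain difference may be the source and stays open, since 0 strain labels occur in both groups, and an effect of Cd24a loss itself and a difference in age or lens size were not tested.

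Of 41 tested genes of the unfolded protein and oxidative stress lists 14 were called, all lower, with a median log2 fold change of -0.48 over these called genes and -0.14 over all 41. Markers of retina and pigment epithelium were lower too, so retinal tissue in the dissected lens was tested by a score of 17 photoreceptor markers, among them Gnb1 at 159 and Gnat1 at 83.0 CPM in wild type. With that score in the model the medians were -0.46 and -0.17. The 14 were picked by their calls, which favours genes that vary little within groups, so their median cannot weigh retinal carry-over. The median of all 41 did not shrink, which argues against retinal carry-over, as scored, as the whole source. The score differed by -0.56 between the groups, knockout minus wild type, with an SD of 0.74 in wild type and 0.34 in the knockout. With the score in the model 4 of the 14 lost their calls, as their median went from -0.41 to -0.37 and their median SE from 0.11 to 0.13. The oxidative stress list went from camera adjusted p = 0.044 to 0.0503 with its median at -0.12. With library size alone, which shifts all genes upward (median 0.114), the median of the 14 was -0.37 (median SE 0.09), and 8 of them stayed called lower. The median of all 41 was then -0.03, and 2 of the 41 were called higher. The unfolded protein list had a median of -0.15 and the oxidative stress list 0.02. Since the 14 were picked by their calls and this scaling moves all genes by a similar amount, these values cannot decide whether scaling is a source. What remains may be scaling, or pigment epithelium (Rgr at 10.7 and Rpe65 at 4.38 CPM in wild type), which was not tested as a covariate. It may also be genotype, strain or handling of the dissected lens, which this design cannot separate.

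The real split of the 6 libraries gave 861 calls and the highest of the other 9 splits gave 2; 1 of 10 splits reached the real count, and with 10 splits no share under 0.05 can be had.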
